A study of Homo sapiens with 4 samples.

How the data were processed

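Gene expression was measured on whole-transcript microarrays in 4 samples of DAOY, an established human medulloblastoma cell line. Per the labels' protocols, cells were exposed for 16 to 24 hours to lentivirus carrying a short hairpin RNA (shRNA), left for 48 hours to recover, and moved into medium with 2 ug/mL puromycin, which kills cells that did not take up the virus. RNA was collected about 48 hours into selection, and 250 ng of total RNA per sample was labelled with biotin. In all, 3 samples received anti-ZFX hairpins named H2, H3 and H4, and 1 sample received a scrambled hairpin with no target. The hairpin sequences were not used here. Each sample was hybridised to 1 array, and nothing in the labels says whether the transductions were repeated.

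The deposited table holds 1 intensity per probe set and array. The authors summarised and normalized the arrays with RMA, per the submitters' processing notes. Its version, settings and software are not given in the sources used here, nor is a genome build, so no coordinates are printed. RMA returns log2 values, but the deposited intensities are on a linear scale, with medians of 228.1, 227.5, 226.0 and 232.3 on the H2, H3, H4 and scrambled arrays. The design had been written for log2 values, so log2 of each intensity was taken before any other step. RMA forces the probe intensities of all arrays onto 1 distribution, which would hide a change of total RNA per cell. No detection call, background value, scan date or slide was used here, so batches could not be examined, and for a dim gene only an intensity filter was available. The number of arrays limits the precision.

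The table has 33297 probe sets. The platform annotation pairs 19460 of them with exactly 1 gene symbol and 1754 with several symbols, and 12083 are not listed with a gene. Of the probe sets with 1 symbol, 19429 matched the RefSeq gene table by gene number and 0 needed a newer symbol. Only these probe sets were used for named genes, so some well-known genes whose probe set carries several symbols are unnamed here. They stand for 18417 genes. For the 769 genes with more than 1 probe set, the one with the highest mean over the 4 arrays was kept. Genes with a mean log2 intensity below the 25th percentile, 6.78, were left out, which left 13813 genes.

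The main comparison set the 3 knockdown arrays, taken as replicates because the labels give them 1 genotype, against the scrambled array with limma's moderated test (lmFit, then eBayes with an intensity trend; limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. This leaves 2 residual degrees of freedom. The spread comes from the 3 hairpins alone and holds hairpin-specific effects, and the lone scrambled array is assumed to vary like the others. The p-values therefore measure only the spread between these arrays. A second count used no test: genes at least 1.5-fold above, or below, the scrambled array with every hairpin, given beside the same count with each other array in its place. Single hairpins against the scrambled array have 1 array a side and were given no p-value. The 34 gene lists, written from general knowledge before the data were examined, were tested with limma's camera where at least 5 genes were kept (33 lists), with a preset correlation between genes of 0.01. An estimated correlation and fry were run as alternatives. Each list's median was also placed among 10000 random lists of its size matched on mean intensity in 20 bins. The members of each list were also adjusted over that list alone, with no correction for the number of lists. Fold differences are knockdown over scrambled, and errors are SDs over the 3 hairpins (n = 3), which leave out the error of the scrambled array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were joined with pandas 2.3.3.

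The test was tried on simulated data, with the real means and hairpin spreads of 13813 genes. In 5 simulations of this 3-against-1 comparison, 149 of 500 genes changed 2-fold and 361 of 500 changed 4-fold were called, with 12 unchanged genes called in all. In 1 further simulation, with nothing changed, 0 genes were called. A list of interferon-stimulated genes lowered by 0.5 on the log2 scale was called in 20 of 20 simulations with the preset correlation and in 0 of 20 with the estimated one, which draws on the 2 residual degrees of freedom. In those runs 2 calls fell on other lists. The simulated genes varied independently, so these runs do not show how often the preset correlation errs for co-regulated genes.

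The genes named in the text follow a rule fixed before the data were examined. They are ZFX, and, among genes on the same side with all 3 hairpins, the 12 with the largest rise and the 12 with the largest fall among those past the threshold. Where fewer than 12 passed, the places were filled by the largest smallest-of-3 difference, given as values. In addition come 2 to 4 members of each list described, or all members of a list of 6 genes or fewer, those past the threshold first and then the largest absolute mean difference, and the 2 highest and 2 lowest genes of each hairpin against the mean of the other hairpins. For H4, 1 of these genes is not reported here. Alternatives fixed beforehand were no filter, a filter at the 50th percentile, quantile normalization again, centring each array on its median, the mean of all probe sets of a gene, eBayes without trend or robust, other thresholds, and leaving out each hairpin. The same limma count with a knockdown array as the lone array was also fixed beforehand. Cyclic loess normalization, and the list test with a knockdown array as the lone array, were chosen after seeing the data. The cause of differences between hairpins could not be traced to their sequences, and no off-target search was made.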

Results

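The arrays addressed how lowering ZFX, a zinc finger transcription factor encoded on the X chromosome, alters gene expression in DAOY medulloblastoma cells. In all, 3 arrays came from cells with an anti-ZFX hairpin (H2, H3 or H4, 1 array each) and 1 array from cells with the scrambled hairpin. Over all 33297 probe sets, log2 intensities of any 2 arrays correlated at 0.992 to 0.996 across probe sets, which are not independent replicates. The closest pair was H3 and scrambled (r = 0.9962), and the most distant was H2 and scrambled (r = 0.9921). No pair of arrays held the same values, with at most 33 identical values between any pair.

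ZFX was lower on all 3 knockdown arrays. Its probe set (8166500) read 1430 on the scrambled array, 744.9 with H2, 749.6 with H3 and 995.6 with H4, or 52.1%, 52.4% and 69.6% of the scrambled value. The mean log2 difference was -0.80 ± 0.24 (SD, n = 3 hairpins; SE 0.22 in limma). Chosen in advance as the targeted gene, ZFX was past the threshold when adjusted over the ZFX family list alone (adjusted p = 0.026 in limma, 2 genes kept) and not over all 13813 genes (adjusted p = 0.9998 in limma). With 4 arrays an exact permutation test of the lone array gives p = 0.25 (two-sided), the smallest it can give. ZNF711, a close relative of ZFX, stood at 98.8%, 99.6% and 100.7% of the scrambled value with H2, H3 and H4. Its mean difference of -0.004 turned positive under each other scaling tried, and the other family member lay under the intensity filter.

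On a list of 6 genes recalled as targets of ZFX named in murine studies, DIS3L, a ribonuclease of the cytoplasmic RNA exosome, had the largest difference. Its probe set (7984298) read 581.0 on the scrambled array and 225.4, 295.0 and 228.5 with H2, H3 and H4, a mean log2 difference of -1.23 ± 0.22 (SD, n = 3) and 42.6% of the scrambled level. UBE2J1, a ubiquitin-conjugating enzyme of the endoplasmic reticulum, was at 59.5%, 57.9% and 82.2% (mean log2 difference -0.61 ± 0.28), and IDH2, mitochondrial isocitrate dehydrogenase, was at 66.5%, 80.1% and 71.4% (mean -0.47 ± 0.14). PTPMT1 differed by -0.055, -0.11 and -0.26, while TBX3 and TCL1A lay on both sides of the scrambled array. Of the 6 genes, 4 were lower with all 3 hairpins and 0 were higher with all 3. DIS3L alone passed when adjusted over the list alone (adjusted p = 0.007 in limma, not corrected for the number of lists), and 0 passed over all genes. The list's median of -0.30 was at the 0.4th percentile of random lists, and camera gave an adjusted p of 0.0267 with the preset correlation. The adjusted p was 0.819 with an estimated correlation. That setting called a list lowered by 0.5 in 0 of 20 simulations, so the value decides nothing. With the preset correlation the adjusted p ranged from 0.00412 to 0.31 over 9 alternatives. The call ended without H4 (0.104) and over genes at or above the 50th percentile of intensity (0.31). The list was recalled from reports on ZFX that may include these arrays, so it is not independent evidence of its direction.

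**Figure D1:**
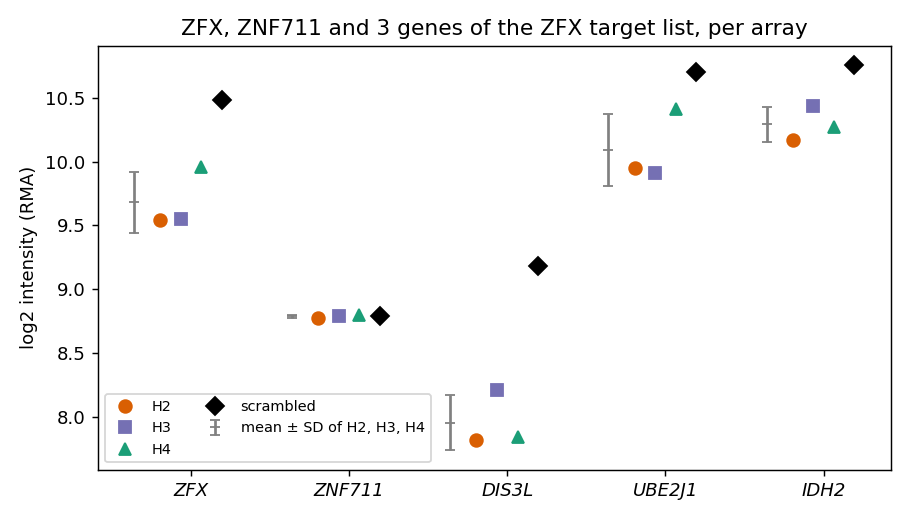
Log2 RMA intensity (vertical axis) of ZFX, its relative ZNF711 and 3 genes of the target list on each of the 4 arrays, with grey bars for the mean ± SD of the 3 knockdown arrays. The scrambled array lies above all 3 knockdown arrays for ZFX, DIS3L, UBE2J1 and IDH2, and level with them for ZNF711, whose mean difference of -0.004 turns positive under other scalings.

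Across the transcriptome the genes lowest relative to the scrambled array with every hairpin were led by IL1B, the inflammatory cytokine interleukin 1 beta, at 26.5% of the scrambled level (mean log2 difference -1.92 ± 0.21, SD, n = 3). Its neighbour IL1A was at 47.3% (-1.08 ± 0.26). The complement component C3 was at 31.4% (-1.67 ± 0.55), with log2 differences from -2.25 with H2 to -1.16 with H3. KYNU, kynureninase of the tryptophan breakdown pathway, was at 46.0%, CTSS, the lysosomal protease cathepsin S, at 47.6%, SRGN, the granule proteoglycan serglycin, at 49.5%, and ANXA3, a calcium-dependent membrane-binding annexin, at 39.2%. CYRIA was at 40.1%, CPA4, a carboxypeptidase, at 53.3%, TIE1, a receptor known from endothelial cells, at 44.6%, and DDX60, an interferon-induced helicase, at 49.5%. DIS3L also belongs to these 12 genes.

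On the other side, DIRAS3, an imprinted small GTPase of the Ras family, was 2.72-fold higher than on the scrambled array (mean log2 difference 1.44 ± 0.31, SD, n = 3), and COX7B, a subunit of cytochrome c oxidase, was 2.48-fold higher (1.31 ± 0.39). HAS2, which makes hyaluronan, was 1.86-fold higher (0.90 ± 0.15), and IGFBP3, a carrier of insulin-like growth factors, 1.67-fold (0.74 ± 0.13). FKBP14, a prolyl isomerase of the endoplasmic reticulum, was 1.61-fold higher with nearly the same value on each knockdown array (0.69 ± 0.034). DYNLRB1, a dynein light chain, and MAPRE3, a microtubule end-binding protein, were both 1.69-fold higher. BSDC1, SUGT1P1, ZNF814, GPC6 and NRROS completed the 12, at 1.53-, 1.65-, 1.47-, 1.46- and 1.44-fold. SUGT1P1 is a pseudogene and ZNF814 belongs to a large zinc finger family, so their probes may read related transcripts. SUGT1P1 also read only 6.88 on the log2 scale on the scrambled array, near the intensity filter at 6.78.

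None of these 24 genes passed the test, and neither did any other gene. In limma 0 of 13813 genes passed an adjusted p of 0.05 (smallest adjusted p = 0.9998), where the same fit with H2 as the lone array called 27, and 446 genes, 343 lower and 103 higher, had an unadjusted p under 0.05, where chance alone gives about 691. By size, 43 genes were at least 1.5-fold below the scrambled array with every hairpin and 7 were at least 1.5-fold above. With another array in the place of the scrambled one, the other 3 arrays were all at least 1.5-fold away at 274 genes for H2, 33 for H3 and 77 for H4, against these 50. Without H2, H3 or H4 in turn, 58, 127 and 95 genes were 1.5-fold lower and 12, 19 and 24 were 1.5-fold higher, since fewer arrays had to pass. Lower was more common than higher in the values as deposited, with 30.6% of genes below and 16.9% above the scrambled array with all 3 hairpins, where chance gives 25% each. Centring each array on its median moved the median of all genes from -0.035 to 0.054, on the other side of zero. It turned these shares to 14.4% and 34.3%, and the 1.5-fold counts to 22 lower and 11 higher. Quantile normalization again left a median of -0.008, shares of 25% and 22%, and 33 lower and 8 higher. Cyclic loess left a median of -0.017, shares of 26.5% and 20.5%, and 35 lower and 8 higher. The reversed balance was thus seen with centring only.

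**Figure D2:**
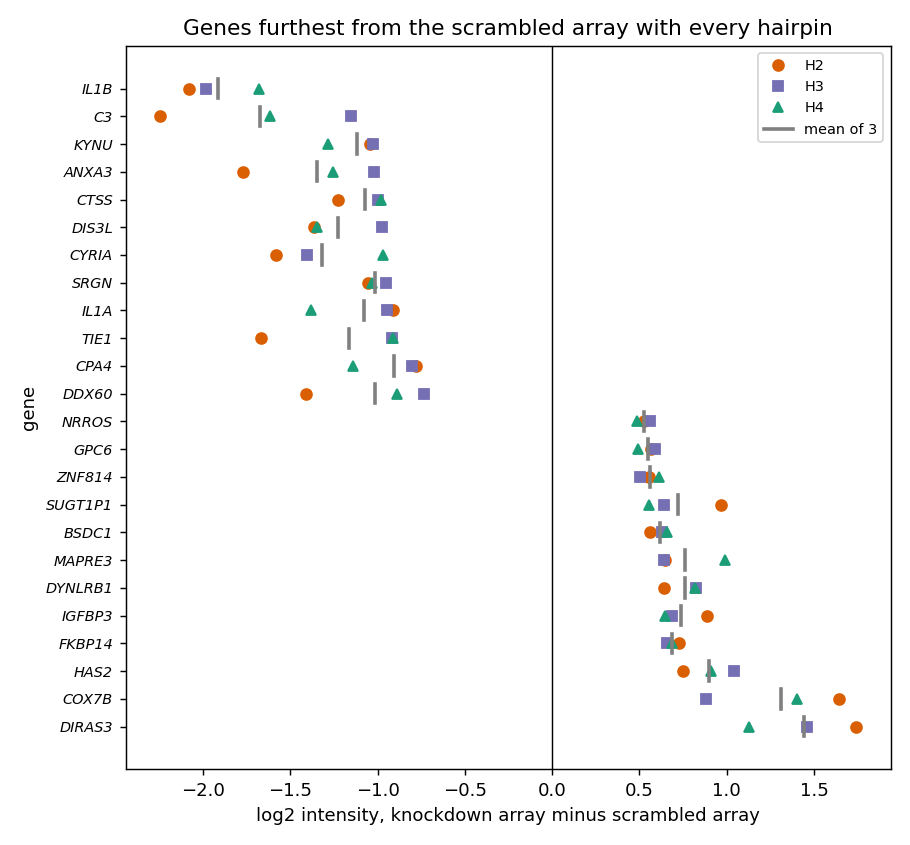
Log2 intensity of each knockdown array minus the scrambled array (horizontal axis) for the 12 genes furthest below and the 12 furthest above it with every hairpin, with grey ticks for the mean of the 3 hairpins. IL1B lies between -2.08 and -1.68 and DIRAS3 between 1.13 and 1.74, and no gene passed the adjusted threshold.

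Genes of inflammatory signalling formed the gene lists furthest below the scrambled array. Of 36 interferon-stimulated genes, 27 were lower with all 3 hairpins and 1 was higher with all 3, and the list median was -0.43. The antiviral effectors MX2, DDX60, IFIT2 and RSAD2 had the largest mean differences. MX2 was at 49.2% of the scrambled level (mean log2 difference -1.02 ± 0.68, SD, n = 3), with log2 differences of -1.80, -0.51 and -0.76 with H2, H3 and H4, and IFIT2 was at 51.8%, with -1.70, -0.62 and -0.54. DDX60 was at 49.5% and RSAD2 at 58.4%. Of 29 genes of NF-kB and cytokine signalling, 14 were lower with all 3 hairpins and 0 were higher, with a median of -0.44. After IL1B came TNFAIP6, a hyaluronan-binding protein, with a mean log2 difference of -1.51 ± 0.95, the chemokine CXCL10 at 41.9%, with log2 differences of -2.17, -0.19 and -1.41 with H2, H3 and H4, and IL1A. Over all genes 0 members of either list passed, and adjusted over the list alone IL1B passed in the cytokine list (adjusted p = 0.003 in limma) and 0 in the interferon list. The list-alone adjustment was not corrected for the number of lists. The hairpins differed in size. The interferon list had medians of -0.72 with H2, -0.28 with H3 and -0.31 with H4, and the cytokine list had -0.65, -0.088 and -0.46. Without H2 the medians were -0.275 and -0.261. With the preset correlation camera gave adjusted p-values of 3.08e-08 and 5.25e-06, and with an estimated correlation both had an adjusted p = 0.819. The estimated correlation called a list lowered by 0.5 in 0 of 20 simulations, so its value decides nothing. Those simulations do not show how often the preset correlation errs for co-regulated genes.

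Besides the ZFX target list, 5 more lists passed camera with the preset correlation, each by a small shift, and 0 of them with an estimated correlation. The estimated correlation called none of the lowered lists in the simulations, so its adjusted p-values below decide nothing either way. With another array in the place of the scrambled one, camera called 8 lists for H2, 2 for H3 and 4 for H4 with the preset correlation, against 8 for the scrambled array. Centring each array on its median kept the direction of the 5 lists but moved their medians to -0.06 (lysosome and autophagy), -0.093 (epithelial), 0.131 (ribosomal), 0.158 (oxidative phosphorylation) and 0.153 (MYC). Lysosome and autophagy genes had a median of -0.15, with 21 of 34 lower and 0 higher with all 3 hairpins (adjusted p = 0.00122 with the preset and adjusted p = 0.819 with an estimated correlation). The largest differences were those of the cathepsins CTSZ (72.8% of the scrambled level, mean log2 difference -0.46 ± 0.18, SD, n = 3) and CTSB (73.5%), of GABARAPL1, an autophagosome protein (80.5%), which rested on H2 and turned positive without it, and of NPC2, a cholesterol-binding lysosomal protein (81.2%). Epithelial markers had a median of -0.18 over 9 genes, 6 of them lower and 0 higher with all 3 hairpins (adjusted p = 0.0219 with the preset and adjusted p = 0.819 with an estimated correlation), led by the keratins KRT8 (68.8%, mean log2 difference -0.54 ± 0.099) and KRT7 (79.2%). Over 8 alternatives the adjusted p of that list ranged from 0.0206 to 0.12, and it was not called without H3 (0.12) or without the intensity filter. In the other direction, genes of oxidative phosphorylation had a median of 0.069, with 26 of 59 higher and 5 lower with all 3 hairpins (adjusted p = 4.17e-05 with the preset and adjusted p = 0.819 with an estimated correlation). The median of this list was 0.089 with H2, 0.002 with H3 and 0.119 with H4. COX7B was its 1 member at least 1.5-fold higher with every hairpin, followed by UQCRH at 127.0% and NDUFS4 at 120.0% of the scrambled level. Cytosolic ribosomal proteins had a median of 0.042, with 24 of 57 higher and 4 lower (adjusted p = 4.54e-06 with the preset and adjusted p = 0.819 with an estimated correlation), such as RPL41 at 122.6% and RPL22 at 118.6%, values that remain uncertain because ribosomal protein genes have many processed pseudogenes. RPL22 also read only 6.84 on the log2 scale on the scrambled array, near the intensity filter at 6.78. MYC target genes had a median of 0.064, with 10 of 32 higher and 2 lower (adjusted p = 0.00933 with the preset and adjusted p = 0.828 with an estimated correlation). The largest mean differences were those of NIP7, which went against the list with log2 differences of 0.045, -0.52 and -0.17 with H2, H3 and H4, and of PUS7, with 0.41, 0.13 and 0.10. The MYC list's medians were 0.20 with H2, 0.044 with H3 and -0.027 with H4, and its median was 0.022 without H2 and 0.11 without H4. Leaving out H2 also moved the ribosomal median to 0.027, and leaving out H3 moved it to 0.064. The MYC list's adjusted p ranged from 0.000469 to 0.376 over 9 alternatives, the highest without H2, when it was not called. Over all genes 0 members of these 5 lists passed, and 0 passed when adjusted over the list alone. Fry called none of the 33 lists (smallest adjusted p = 0.556), and it was not tried in the simulations.

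Of the lists that camera did not call, G1/S genes were among the nearest to the threshold. With all 3 hairpins, 20 of 41 were lower and 3 higher (median -0.11, adjusted p = 0.0569), among them GINS1 at 74.3%, UHRF1 at 75.2% and MCM2 at 78.3% of the scrambled level. Genes of the unfolded protein and integrated stress response had the same adjusted p (median -0.098, 18 of 38 lower and 1 higher with all 3 hairpins). DDIT4 was at 66.2%, and the disulfide isomerase PDIA4 had log2 differences of -0.24, -0.16 and -0.94 with H2, H3 and H4. Among p53 target genes (median -0.15, adjusted p = 0.236), TP53INP1 was at 59.7%, whereas MDM2, which restrains p53, was at 152.9%, each on 1 side with all 3 hairpins. The adjusted p was 0.172 for cholesterol synthesis (median -0.11, with 0.077 on H2, -0.12 on H3 and -0.29 on H4), with INSIG1 at 71.5% and HMGCS1 at 0.077, -0.35 and -0.48 on the log2 scale with H2, H3 and H4. It was 0.617 for the small RNA machinery (median -0.13), with DICER1 at 72.1% and AGO4 at 74.3%. Centring each array on its median kept these medians negative but moved them toward zero, to -0.019 for G1/S genes, -0.009 for the stress response, -0.056 for p53 target genes, -0.019 for cholesterol synthesis and -0.042 for the small RNA machinery. Single hairpins also set their size. Without H2 the median was -0.043 for G1/S genes, -0.22 for cholesterol synthesis and -0.061 for the small RNA machinery. Without H4 it was -0.024 for cholesterol synthesis, -0.07 for the small RNA machinery and -0.055 for the stress response, which had -0.16 without H3.

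In several other uncalled lists some of the genes with the largest mean differences rested mainly on 1 hairpin, and for these the log2 differences are given in the order H2, H3 and H4. Extracellular matrix genes had a median of -0.21 (adjusted p = 0.117), with -0.39 on H2, -0.095 on H3 and -0.083 on H4. The proteoglycan BGN differed by -1.68, -0.11 and -0.054, and TIMP3, a metalloproteinase inhibitor, by -1.18, -0.089 and -0.52. In the Notch pathway (median -0.095, adjusted p = 0.172) LFNG was at 72.0% of the scrambled level and NOTCH2 differed by -0.76, -0.12 and -0.19. Among WNT pathway target genes (median -0.12, adjusted p = 0.335) DKK1, an inhibitor of the pathway, differed by 1.11, 0.34 and -0.096, and CCND1, cyclin D1, by -1.06, -0.18 and -0.052. Haematopoietic markers had a median of -0.10 (adjusted p = 0.298), with LCP1 at 44.7% and LAPTM5 at -1.60, -0.37 and 0.071. Endothelial markers had a median of -0.096 (adjusted p = 0.208), with TIE1 at 44.6% and TEK at -1.08, -0.30 and -0.25. The RNA exosome and decay list had a median of 0.017 and a mean of -0.065 (adjusted p = 0.903), with DIS3L at 42.6% and XRN1 at -0.61, -0.29 and 0.02. The glial and neural stem cell list had a median of 0.006 and a mean of -0.09 (adjusted p = 0.935), with CSPG4 at -1.37, -0.29 and -0.60 and CNP at -0.23, -0.90 and -0.06. Centring each array on its median kept the signs of these medians but moved them to -0.125 (extracellular matrix), -0.006 (Notch), -0.028 (WNT), -0.014 (haematopoietic), -0.007 (endothelial), 0.106 (RNA exosome and decay) and 0.095 (glial and neural stem cell). Without H2 the median was -0.10 for extracellular matrix and -0.077 for WNT target genes, and without H4 it was -0.066 for haematopoietic markers. The RNA exosome median turned negative without H2 (-0.027) and without H3 (-0.001), and the glial median turned negative without H2 (-0.025), H3 (-0.007) or H4 (-0.034).

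The remaining lists had medians whose sign turned under centring or another scaling. Centring each array on its median, which moved the median of all genes from -0.035 to 0.054, turned the following negative medians positive. With quantile normalization again and with cyclic loess the medians in this paragraph stayed negative. Values with H2, H3 and H4 are again log2 differences in that order. Hedgehog pathway genes, the pathway active in one class of medulloblastoma, had a median of -0.044 (adjusted p = 0.903), with SMO, its signal transducer, at -0.32, -0.15 and -0.71 and DISP1 at 76.2% of the scrambled level. G2/M genes had a median of -0.024 (adjusted p = 0.903), with the checkpoint kinase BUB1 at 81.8% and CDCA2 at -0.38, -0.17 and -0.096. Replication-dependent histones, near-identical genes whose probe sets remain uncertain, had a median of -0.034 (adjusted p = 0.674), with H2BC7 at 123.7% and H3C10 at -0.49, -0.31 and -0.077. Camera's direction was upward for both lists and for housekeeping genes (median -0.006, adjusted p = 0.903), in which SDHA differed by -0.27, -0.094 and -0.095 and GUSB by -0.35, -0.013 and -0.094. Neuronal genes had a median of -0.083 (adjusted p = 0.903), with the neurofilament NEFL at 151.7%, ENO2 at -1.13, -0.13 and -0.46, and INA at 1.28, 0.24 and -0.26. For hypoxia and glycolysis, which also holds ENO2, the median was -0.079 (adjusted p = 0.326), with NDRG1 at -0.74, -0.48 and 0.017. Without H2 the median was -0.002 for Hedgehog, -0.002 for G2/M and 0 for histone genes, and -0.029 for housekeeping genes, which had 0.008 without H3. Without H4 it was -0.074 for Hedgehog, -0.041 for G2/M, -0.068 for histone genes and -0.049 for hypoxia and glycolysis.

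Centring also turned positive the medians of apoptosis regulators (-0.077, adjusted p = 0.8), immediate early genes (-0.075, adjusted p = 0.878), TGF-beta target genes (-0.044, adjusted p = 0.999) and ER-associated degradation (-0.031, adjusted p = 0.935). With quantile normalization again and with cyclic loess the medians of these lists stayed negative. Among apoptosis regulators, the death-promoting PMAIP1 differed by -1.65, -0.66 and -0.62 with H2, H3 and H4, and BMF by -1.23, -1.02 and 0.41. Of the immediate early genes, SGK1 was at 134.5% and DUSP5 differed by -0.72, -0.28 and -0.25. TGFB2 was at 58.0%, and TAGLN, a TGF-beta target and muscle marker, differed by -1.35, 0.41 and -1.06. In ER-associated degradation, UBE2J1 was at 65.7% and DERL1 differed by -1.11, -0.27 and 0.001. For granule neuron progenitor and cerebellar genes (median -0.028, adjusted p = 0.999), with PAX6 at -0.58, -0.33 and -0.072 and EN1 at 86.2%, each other scaling turned the sign. The same held for muscle markers (median -0.001, adjusted p = 0.935), which hold TAGLN and, at 77.2%, CNN1. The proteasome list (median 0.004, adjusted p = 0.117), with PSMA1 at 117.4% and PSMA4 at 111.4%, turned negative with quantile normalization again and with cyclic loess. Leaving out 1 hairpin moved the median of 24 of the 34 lists by over 1.5 times and turned the sign of 6. In this paragraph, the TGF-beta median was 0.041 without H2, the granule neuron progenitor median 0.002 without H4, the proteasome median -0.008 without H3 and the muscle median -0.10 without H3. The median of immediate early genes was -0.043 without H2, and that of apoptosis regulators was -0.13 without H3 and -0.049 without H4. Over all genes 0 members of any uncalled list passed, and adjusted over the list alone only DIS3L passed, in the RNA exosome and decay list. That adjustment was not corrected for the number of lists. DIS3L is the same gene that passed in the ZFX target list, so this is not a second result.

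**Figure D3:**
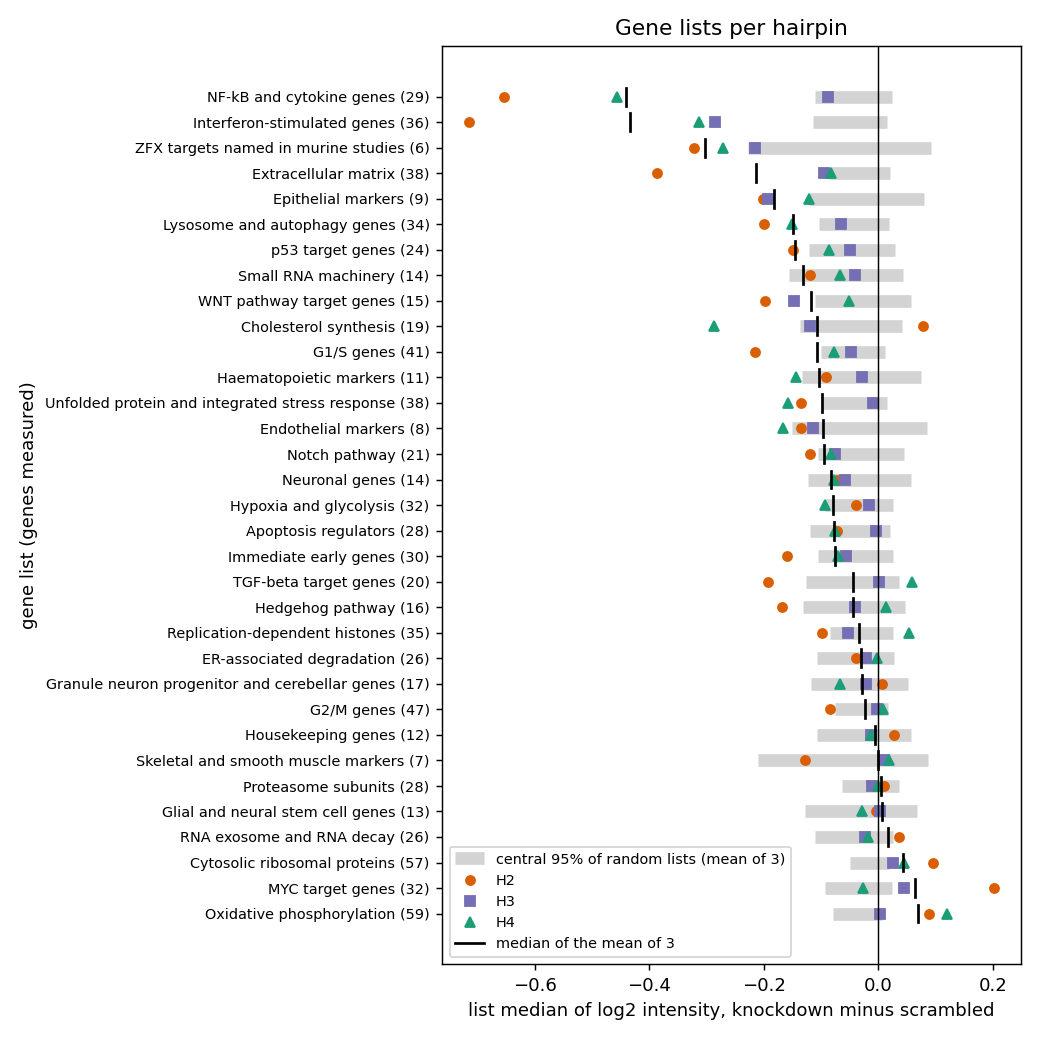
Median log2 difference from the scrambled array (horizontal axis) of 33 gene lists, with 1 symbol per hairpin, a black tick for the median of the 3-hairpin mean and a grey bar for the central 95% of random lists matched on intensity. The interferon and cytokine lists lie furthest below zero, at -0.43 and -0.44, with H2 below H3 and H4 in both.

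The arrays of the 3 hairpins differed in how far they lay from the scrambled array. H2, compared with the scrambled array alone, had 213 genes at least 2-fold away, 192 of them lower, against 24 for H3 and 54 for H4. ZFX stood at 52.1% of the scrambled level with H2, 52.4% with H3 and 69.6% with H4. Relative to the mean of the other hairpins, LYPD6B was lowest with H2 (log2 difference -2.28), followed by TMOD1, an actin filament capping protein (-2.20). FAM133A (1.78) and FST, the activin antagonist follistatin (1.60), were highest with H2. FAM133A read only 6.87 on the log2 scale on the scrambled array, near the intensity filter at 6.78. VCAM1, an adhesion molecule, and ACTA2, smooth muscle actin, were highest with H3, at 1.75 and 1.73, with the mean ACTA2 difference from the scrambled array turning negative without H3. MGP, an inhibitor of calcification (-2.20), and SLC26A2, a sulfate transporter (-1.19), were lowest with H3. Against the scrambled array, VCAM1 differed by -1.68, 0.41 and -0.985 with H2, H3 and H4, and MGP by 2.05, -0.27 and 1.81. MGP thus stood out with H3 because it was higher with H2 and H4, and VCAM1 mainly because it was lower with them. CCKAR, the cholecystokinin receptor, and CH25H, cholesterol 25-hydroxylase, were highest with H4, at 2.64 and 2.17, and COA6 (-1.38) was among the lowest. These values compare 1 array with others and have no replicate check.

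Across genes, which are not independent replicates, the differences from the scrambled array correlated at 0.497 between H2 and H3, 0.396 between H2 and H4 and 0.379 between H3 and H4. Because the 3 differences share the scrambled array, simulated arrays with no effect gave 0.501. The covariances were 0.0309, 0.0273 and 0.017, below the simulated 0.0374. A single control array could not be split, so part or all of the correlation may come from that shared array. The simulated spread also holds hairpin-specific effects, which raises the simulated covariance.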

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

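The tests in this part, cyclic loess normalization included, were chosen after the patterns were seen, and only the count of 1.5-fold genes with each other array as the lone array was fixed before the data were examined.

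The interferon and cytokine lists lay below the scrambled array, a pattern that 1 odd array on either side could produce. Leaving out H2 left medians of -0.275 (interferon) and -0.261 (cytokine), below the central 95% of random lists (-0.097 to 0.014 and -0.096 to 0.024), which are not matched on co-regulation, and this argues against the H2 array alone. The scrambled array alone does not account for the further drop with H2, since the interferon list on H2 differed from the mean of H3 and H4 by a median of -0.449 (random lists -0.097 to 0.068). Against a response graded by the ZFX level stand H2 and H3, which had nearly the same ZFX reading and differed by -0.433 on the interferon and -0.515 on the cytokine list, and the cytokine medians of -0.088 with H3 and -0.46 with H4, which had more ZFX, but with 1 array per hairpin this stays open. For the difference with H3 and H4, an odd scrambled array and an effect of ZFX knockdown cannot be told apart with 1 scrambled array, and the interferon gap between knockdown arrays is larger than that difference.

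The H2 array stood apart from the other 3. ZFX with H2 was only -0.009 from its level with H3, so the ZFX reading did not set H2 apart from H3. With 1 array per hairpin, a lower ZFX level as the cause stays open. A large intensity-dependent difference in scaling is argued against by the median of H2 minus scrambled, which ranged only from -0.076 to 0.026 over groups of genes ordered by intensity. After cyclic loess normalization 272 genes, against 274 before, were 1.5-fold from H2 in the other 3 arrays. With so small a trend to remove, that count could hardly have moved, so it decides nothing further. Also open are a sequence-specific effect of the H2 hairpin and a difference of that culture or array. Neither was tested.

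Of the 4 arrays, 3 gave at least as many 1.5-fold genes as the lone array as the scrambled array did, itself included: the real count was 50 and the highest other was 274, for H2. The count for H2 is several times the real one and points to a structure of these arrays, in which H2 stands apart. With 4 splits no share under 0.05 can be had.

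Probe sets not listed with a gene were outside the comparisons, and among the 5808 of them above the intensity filter, 62 were at least 1.5-fold above the scrambled array with every hairpin and 18 were below. With H2, H3 or H4 as the lone array, the other 3 arrays were all higher at 46, 11 and 22 of them and all lower at 35, 5 and 21, so that the total was 81 for H2 and 80 for the scrambled array.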

How the results depend on the processing

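The ZFX level, as the mean log2 difference, stayed between -0.936 and -0.709 under all 11 alternatives, never past the adjusted threshold. The count of genes past it was 0 under 15 of 16 alternatives, including an adjusted p of 0.10, and 27 with H2 as the lone array. Genes 1.5-fold higher with every hairpin numbered 11 after centring each array on its median and 1 at 2-fold. Genes 1.5-fold lower numbered 22 after centring, 28 above the 50th percentile of intensity and 4 at 2-fold. Leaving out 1 hairpin gave 12 (without H2) to 24 (without H4) higher and 58 (without H2) to 127 (without H3) lower, since fewer arrays must pass. The number of gene lists called was 7 to 11 with the preset correlation, but 0 with an estimated correlation and 0 with fry, and it was 2 with H3 and 4 with H4 as the lone array, against 8 with the scrambled array and 8 with H2. Genes at unadjusted p under 0.05 ranged from 248 above the 50th percentile to 691 with no filter, and were 1851, 319 and 636 with H2, H3 and H4 as the lone array. Among named genes, ZNF711 moved from -0.004 to 0.035 with quantile normalization again, 0.085 after centring and 0.025 with cyclic loess, and leaving out 1 hairpin gave -0.011 to 0.002. Leaving out H3 turned ACTA2 (-0.373 to 0.738 over the 3 omissions), leaving out H2 turned BOC (-0.821 to 0.024), GABARAPL1 (-0.536 to 0.046) and INA (-0.008 to 0.761), and the cause was not tested. Counts of 2-fold genes per hairpin stayed within 1.5 times under 6 alternatives. With 2 residual degrees of freedom and 1 control array, most genes changed 2-fold were missed in the simulations. The list test with an estimated correlation called 0 of 20 lowered lists there, so its count of 0 decides nothing. No paired analysis was possible because the scrambled group holds 1 array. Cyclic loess and the list tests with a knockdown array as the lone array were chosen after seeing the data.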

Other observations

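The test of neighbouring genes was chosen after the 50 genes were known and before its own result was seen. Among the 50 genes at least 1.5-fold from the scrambled array with every hairpin were the leukotriene pathway protein ALOX5AP, with log2 differences of -1.07, -0.93 and -0.70 with H2, H3 and H4, and the transporter SLC46A3, with -0.71, -0.67 and -0.99. TSPAN15, a membrane tetraspanin, differed by -0.73, -0.75 and -0.83. These genes are named because each lies near another of the 50 on its chromosome, and they were chosen after their values were seen.

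A hypothesis was that the 50 genes lie beside each other in the genome more than chance gives. In the order of measured genes on each chromosome (RefSeq gene table, GRCh38.p14), 3 pairs lay within 5 places of each other: IL1A with IL1B, ALOX5AP with SLC46A3, and SRGN with TSPAN15. Of 1000 random draws matched on intensity, 5.9% gave as many or more, with a median of 1, so chance draws reached the same count and the test does not decide. The lower signal of DIS3L did not extend to its nearest measured neighbours: TIPIN differed by 0.019, -0.14 and 0.17 and MEGF11 by -0.055, 0.027 and -0.13 with H2, H3 and H4.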
